A study of Caenorhabditis elegans with 4 samples.

How the data were processed

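Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was used to map where NHR-2, a nuclear hormone receptor, sits on the genome of Caenorhabditis elegans embryos. Per the labels, the strain carried an nhr-2 transgene whose product ends in a green fluorescent protein (GFP) tag, together with an unc-119 rescue marker, and the worms were grown at 20 °C. Per the labels' protocols, worms were crosslinked in 2% formaldehyde, chromatin was sheared by sonication, and the tagged protein was collected with an anti-GFP antibody. A portion of each lysate was kept as input DNA. The labels describe 4 libraries, 2 of ChIP DNA and 2 of input DNA, numbered 1 and 2 in each group. Nothing in the labels says whether the replicates came from separate cultures, so the spread between them may be technical.

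The authors deposited 3 peak lists, which are the data used here: 1 for each ChIP library and 1 combined list of the series. The input libraries entered, if at all, through the authors' peak calling, and no input values were analysed here. Per the file headers, coordinates are on the WormBase WS220 build. The source column of the deposited files names the SPP peak caller with the irreproducible discovery rate, a method that keeps peaks whose rank is alike in replicates. The aligner, the software versions, the thresholds and the way in which the combined list was made are not given in the sources used here. Each peak carries a score and a peak number, as deposited by the authors, and the scale of the score is not stated. Taken as a negative exponent of 10, the lowest score of both replicate lists gave 0.990, the highest value reached, which is how the −log10 of a false discovery rate capped near 1 would look. Peak numbers ran from 1 to the length of the list, and the peaks tied at the highest score held the lowest numbers in each list. Spearman's correlation between peak number and score was −1.00 in both replicate lists and −0.75 in the combined list, where ties dominate. Peak number 1 was therefore read as the strongest peak, and scores were compared only within a list. Read numbers and library depths are unknown, so no counting interval can be given for the height of a peak.

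Overlaps were counted between intervals that shared at least 1 bp. To set the level that random overlap would give, 1 list was rotated along each chromosome by a random distance, 10000 times, and the p-value is the one-sided share of rotations with at least as much overlap. The smallest p-value this allows is 0.0001. Pairs of replicate peaks that were mutually nearest and overlapped were used to compare ranks. Peak densities used the length of each chromosome up to its last deposited peak, because WS220 chromosome lengths were not used here. For the chromosome test, peaks whose centres lay within 10 kb of the next were kept together as a cluster, clusters were placed at random 10000 times in proportion to chromosome length, and two-sided p-values were adjusted by the Benjamini-Hochberg method over the 6 nuclear chromosomes. The smallest unadjusted p-value here is 0.0002. The same placement gave the expected share of peaks in the middle 50% of a chromosome. Intervals on density ratios came from resampling blocks of 1 Mb, 10000 times, separately for X and the other chromosomes. Binomial intervals are exact (Clopper-Pearson, 95%). They cover counting error only and treat peaks as independent, which clustered peaks are not.

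The overlap counts, the rotation test and the placement test were tested on simulated data. Overlap counts matched those of bedtools in every simulated comparison. With unrelated lists, 8.33% of 60 rotation tests gave p under 0.05. With peaks placed evenly, 6.67% of 60 placement tests did, and with X density raised 1.5 times 91.7% did. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and bedtools 2.31.1 were used.

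The tests, the alternatives and the regions to be named were chosen before the data were examined, except where stated in the closing section. Planned tests of peaks at promoters, in 25 fixed gene lists and for shared sequence words needed a genome and annotation of WS220. The gene table at hand is of WBcel235, a different build, and gives no strand. Peaks were therefore not assigned to genes and these tests, with their gene lists, were not run. In that case the rule named the 10 combined peaks with the lowest peak numbers, by position. Splits planned by score were made by peak number, since 1737 of the 2299 combined peaks share 1 score. No genic, exonic or intronic annotation is given for any region for the same reason.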

Results

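Peak lists from 2 anti-GFP ChIP-seq libraries of Caenorhabditis elegans embryos carrying GFP-tagged NHR-2 were compared with each other and with the combined list of the series, to describe the in vivo binding regions of this nuclear hormone receptor. Nuclear hormone receptors are zinc-finger transcription factors, a family that is much expanded in nematodes. The replicate 1 list held 29379 peaks and the replicate 2 list 24151 peaks. The combined list held 2299 peaks, which merged into 2248 regions where intervals overlapped. Most peaks had a fixed width, which was 400 bp in replicate 1, 470 bp in replicate 2 and 450 bp in the combined list. No combined interval was identical to an interval of either replicate. The score reached a ceiling in every list. In replicate 1, 2353 peaks were tied at 3.67, in replicate 2, 990 peaks at 3.30, and in the combined list 1737 peaks at 3.54. The read depth of the libraries is unknown.

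The strongest region by peak number lay on chromosome I. The 3 combined peaks with the lowest numbers stood side by side there, at positions 5822471 to 5823027, 5820357 to 5820865 and 5821062 to 5821568 on WS220. They were peaks 1, 2 and 3 in replicate 1 and peaks 1, 2 and 5 in replicate 2. They belonged to a cluster of 7 combined peaks between 5818789 and 5829231. Chromosome I also held the fourth combined peak at 8138557 to 8139081 (peak 5 in replicate 1 and peak 3 in replicate 2), the sixth at 10585229 to 10585742 (peaks 4 and 9) and the ninth at 14960130 to 14960713 (peaks 7 and 12). On chromosome III, the fifth combined peak spanned 8795518 to 8796028 (peaks 9 and 4) and the seventh 3871722 to 3872186 (peaks 8 and 6). The eighth lay on chromosome IV at 7022949 to 7023352 (peaks 6 and 10), and the tenth on chromosome V at 6684546 to 6685051 (peaks 16 and 7). All 10 of these peaks were at the ceiling of the score in the combined list and, through their best overlapping peak, in both replicates, so only the peak number orders them. They were 404 to 584 bp wide. The transgene also carries nhr-2 and unc-119. Whether any of these 10 peaks lies at either locus was not checked for want of WS220 genes. The 3 strongest, on chromosome I, can therefore not be called binding regions apart from the transgene. A peak at either locus could not be told apart from signal of the transgene.

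The first comparison asked how far the replicates found the same regions. Most of the strongest regions were shared, and the share fell as tops longer than 200 peaks were compared. Of the 100 strongest peaks of each list, 75% overlapped one of the 100 strongest of the other. Of the 200 strongest peaks of replicate 1, 161 (80.5%) overlapped one of the 200 strongest of replicate 2, and 162 (81.0%) did in the other direction. Among the strongest 1000 of each list the shares were 71.9% and 72.2%, and among the strongest 10000 they were 45.3% and 46.5%. The full lists consisted largely of low-scoring peaks. Their median score was 0.252 in replicate 1 and 0.067 in replicate 2, against ceilings of 3.67 and 3.30. Over the full lists, 12434 replicate 1 peaks (42.3%, 95% interval 41.8 to 42.9%) overlapped a replicate 2 peak, and 12531 replicate 2 peaks (51.9%, 51.3 to 52.5%) overlapped a replicate 1 peak. Random rotation of a list gave a mean of 18.9% and 23.1%, and no rotation reached the observed share in either direction (one-sided p = 0.0001 by circular permutation, the smallest that 10000 rotations can give; n = 29379 and n = 24151 peaks). With both lists limited to their strongest 2299 peaks the shares rose to 65.0% and 66.0%, against 2.37% and 2.45% after rotation. Peak order agreed in part. Across 10863 matched pairs, Spearman's rho of the peak numbers was 0.52 and Pearson's r of their log10 values was 0.73. These are correlations across peaks, which are not independent replicates. Among pairs from the strongest 2299 peaks of each list rho was 0.71 over 1461 pairs.

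**Figure D1:**
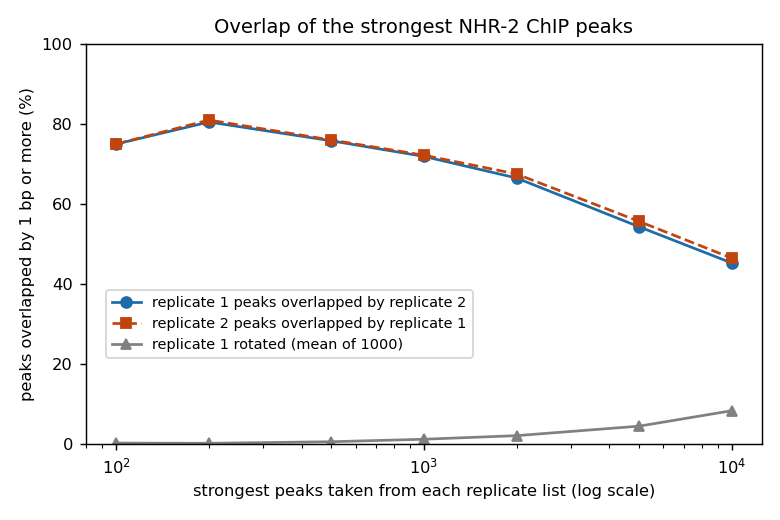
Share of the strongest peaks of each replicate list (y axis, percent) that overlapped the equally long top of the other list by at least 1 bp, against the number of peaks taken (x axis, log scale). Circles and squares are the 2 directions and triangles the mean after random rotation; the share is 75% in both directions at 100 peaks and falls from 80.5% and 81.0% at 200 peaks to 45.3% and 46.5% at 10000.

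The second comparison asked what the combined list kept. Nearly every combined peak was seen in both libraries. Replicate 1 overlapped 2294 of the 2299 combined peaks (99.8%, 95% interval 99.5 to 99.9%) and replicate 2 overlapped 2279 (99.1%, 98.7 to 99.5%). Both did for 2274 peaks, and no combined peak lacked an overlap in both. Rotation gave means of 21.4% and 18.9% (n = 2299 peaks, p = 0.0001 for each by circular permutation, the smallest possible). Because the combined list belongs to the same series, this overlap shows what was kept and is not an independent repeat. The best overlapping replicate peak had a median number of 1147 in replicate 1 and 1145 in replicate 2, and 2078 combined peaks (90.4%) were matched within the first 5000 of both lists. A minority was weak in one library, with 51 combined peaks matched only beyond number 5000 in replicate 1 and 146 in replicate 2. In the other direction, 98.1% of the strongest 1000 replicate 1 peaks and 98.4% of those of replicate 2 overlapped a combined peak. For the strongest 2299 the shares were 82.9% and 78.5%.

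The third comparison asked where in the genome the combined peaks lie. In the combined list X carried the most peaks and chromosome V the fewest relative to length, though the first place of X did not hold in replicate 2. X held 527 peaks, 29.7 per Mb, or 1.30 times its share by length (n = 1319 clusters placed at random, adjusted p = 0.0006). Chromosome V held 304, 14.5 per Mb and 0.63 times its share (adjusted p = 0.0006, n = 1319 clusters), and chromosome IV held 309, 17.7 per Mb and 0.77 times its share (adjusted p = 0.008). The strongest 2299 peaks of both replicates gave the same directions for X, V and IV, but in replicate 2 chromosomes III (28.7 per Mb) and I (27.8 per Mb) were denser than X (26.4 per Mb). Chromosomes III (27.4 per Mb, adjusted p = 0.0534), I (26.8 per Mb, adjusted p = 0.0679) and II (24.7 per Mb, adjusted p = 0.367) did not pass the same test (n = 1319 clusters). In the stronger 50% of the combined list (n = 1149 peaks) the density of chromosome IV missed the threshold, at 0.79 times its share (adjusted p = 0.0568), while X and V passed it.

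Peak density on X was 1.39 times that of the autosomes together (29.7 against 21.5 per Mb), with a block bootstrap interval of 1.15 to 1.66. Much of this ratio came from IV and V, as a split chosen after the result was seen showed. Against IV and V (16.0 per Mb) X was 1.86 times denser (1.48 to 2.36), whereas against I to III (26.3 per Mb) the ratio was 1.13 and its interval, 0.95 to 1.35, included 1. Both libraries gave a ratio above 1. It was 1.51 (1.27 to 1.80) for the strongest 2299 peaks of replicate 1 and 1.203 (0.997 to 1.44) for those of replicate 2, leaving out mitochondrial peaks, a mean of 1.36 ± 0.22 (SD, n = 2). The X excess was found at peak numbers up to 1000 of both lists and not beyond number 5000 of either. X held 22.2% of the 495 nuclear peaks at peak numbers 1 to 500 of replicate 1 and 27.3% of the 495 at 501 to 1000. In replicate 2 these shares were 22.8% and 24.4%. Beyond peak number 10000, X held 17.1% in replicate 1 (95% interval 16.6 to 17.6%) and 16.1% in replicate 2 (15.5 to 16.7%), and X makes up 17.7% of the nuclear length. In between, the replicates differed. At peak numbers 1001 to 2299, X held 24.4% (22.1 to 26.8%) in replicate 1 and 18.1% (16.1 to 20.4%) in replicate 2. At 2300 to 5000 it held 19.6% (18.1 to 21.2%) and 16.9% (15.5 to 18.4%).

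**Figure D2:**
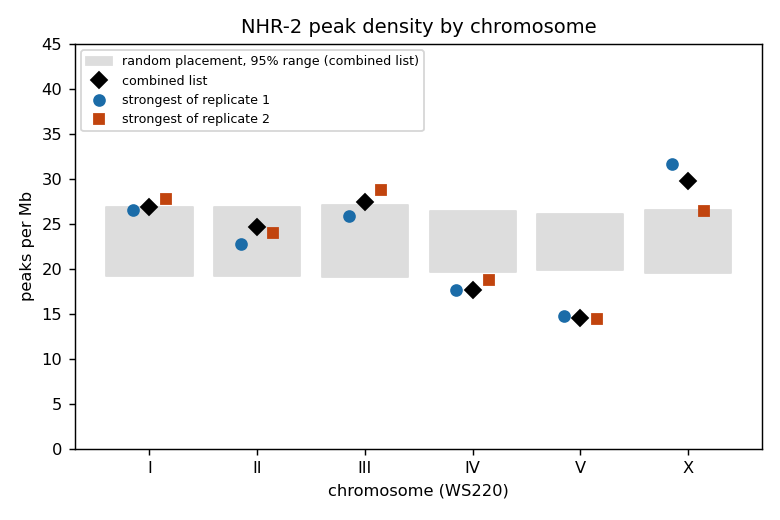
Peaks per Mb (y axis) on each nuclear chromosome (x axis). Diamonds are the combined list, circles and squares the strongest 2299 peaks of replicate 1 and replicate 2, and grey bars the 95% range of 10000 random placements of the combined clusters; IV and V lie below their range in all 3 lists, X lies above it in the combined list and replicate 1, III in the combined list and replicate 2, and I in replicate 2.

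**Figure D3:**
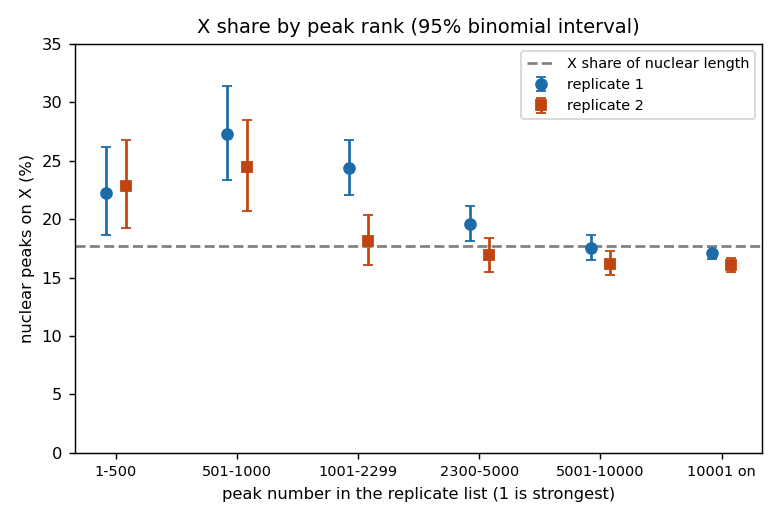
Percent of nuclear-chromosome peaks on X (y axis) by peak number in the replicate list (x axis), with exact 95% binomial intervals. The dashed line is the X share of nuclear length, 17.7%; the shares at peak numbers up to 1000 lie above it and those beyond number 5000 at or below it.

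Combined peaks were more frequent in the middle of chromosomes than toward their ends. The middle 50% of the chromosomes held 1306 of the 2299 peaks, 56.8%, against 46.5 to 53.5% in 95% of random placements (n = 1319 clusters, p = 0.0006, two-sided). Taken one by one, only chromosome III passed the test after adjustment over the 6 chromosomes (62.4%, n = 378 peaks, adjusted p = 0.0168). Chromosomes V (61.8%, adjusted p = 0.069), II (59.7%, adjusted p = 0.0812), I (56.9%, adjusted p = 0.17) and IV (53.4%, adjusted p = 0.605) did not, nor did X (49.7%, adjusted p = 0.954), with n = 304 to 527 peaks each. The strongest 2299 peaks of each replicate gave 56.0% ± 2.4 (SD, n = 2) in the middle 50%. Among peaks beyond number 10000 the share was 46.1% in replicate 1 and 42.5% in replicate 2. The densest bins of 500 kb were on V from 11500001 to 12000000 (31 peaks), on I from 9500001 to 10000000 (30 peaks) and on X from 10500001 to 11000000 (30 peaks). The cluster with the most peaks, 12, lay in the first of these, on V at 11947311 to 11964479.

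**Figure D4:**
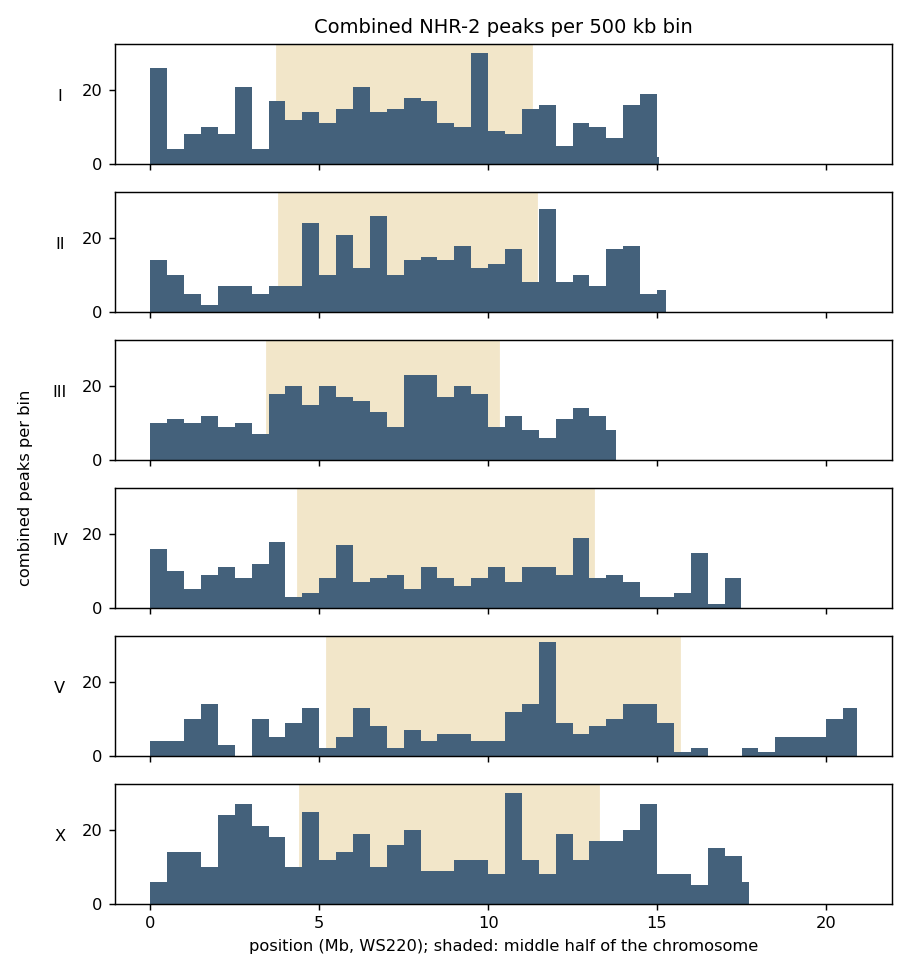
Number of combined peaks (y axis) in bins of 500 kb along each nuclear chromosome (x axis, Mb on WS220), with the middle 50% of each chromosome shaded. The tallest bars, 31 peaks on V and 30 each on I and X, stand near 11.5, 9.5 and 10.5 Mb.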

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

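The tests of rank and of omission in this part were chosen after the result was seen, and the coverage test after the mitochondrial peaks had been seen but before its own value was known. Both replicate lists held peaks on the mitochondrial chromosome, 25 in replicate 1 and 24 in replicate 2, and the combined list held 0; the overlap of the replicates counts them, and no chromosome comparison does. In replicate 1 the strongest were peak 12 at 12178 to 12770 and peak 20 at 12986 to 13324, and in replicate 2 peak 29 at 12925 to 13330 and peak 52 at 12326 to 12478. Low rank does not account for their absence, since of the replicate 1 peaks that were within number 1000 in both lists, all 712 nuclear ones (100%) and 0 of 7 mitochondrial ones overlapped a combined peak. Whether the mitochondrial chromosome was left out when the combined list was made stays open, because Fisher's exact test of that contrast (two-sided p = 5.22e-17) restates the count of 0 that prompted it. Peaks covered 46.9% of the mitochondrial length in replicate 1 and 55.5% in replicate 2. In either replicate 0% of 7227 nuclear windows of the same length were covered as fully (highest 46.1% and 45.5%). Called peaks were thus denser there than in any nuclear window, though narrowly so in replicate 1. Coverage by called peaks cannot tell signal over much of the molecule from many separate sites. Whether this coverage came from the ChIP or from the input libraries cannot be read from peak lists, and no biological explanation was tested.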

How the results depend on the processing

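All 4 overlap shares stayed above every rotation under a reciprocal overlap of 50%, centres within 200 bp, the stronger 50% of each list and lists limited to 2299 peaks; the replicate shares ranged from 29.8% to 65.0% (replicate 1) and from 36.2% to 66.0% (replicate 2), and the shares of combined peaks from 83.1% to 100% (in replicate 1) and from 77.6% to 99.8% (in replicate 2). Leaving out mitochondrial peaks, an alternative chosen after seeing the data, gave 42.3% and 51.9%. Spearman's rho of shared peaks moved from 0.52 to 0.58 with centres within 200 bp, 0.65 in the stronger 50% of each list and 0.71 in lists limited to 2299 peaks, where fewer weak peaks enter by construction. The X to autosome ratio was 1.57 in the stronger 50% and 1.39 with overlapping peaks merged (chosen after seeing the data). To leave out 1 replicate, the strongest 2299 peaks of the other replaced the combined list, which was not made anew. These are the values given above, 1.203 for replicate 2 (n = 2280 nuclear peaks, adjusted p = 0.0427) and 1.51 for replicate 1 (n = 2282, adjusted p = 0.0006). In this top of replicate 2 (n = 2280 nuclear peaks), chromosomes I (1.22 times its share by length, adjusted p = 0.0188) and III (1.26 times, adjusted p = 0.0114) also passed the test and lay above X (1.16 times). I and III also passed with peaks placed one by one (n = 2299 peaks, adjusted p = 0.0012 and 0.0003) and III, chosen after seeing the data, with each cluster counted once (n = 1319 clusters, adjusted p = 0.0162). Both passed (n = 2238 peaks, adjusted p = 0.0339 and 0.032) and lay above X with the 10 X clusters of most peaks left out, also chosen after seeing the data, but a removal on X alone lowers X and raises the others by construction. The share of peaks in the middle 50% ranged from 54.3% to 58.6% and passed the test in each alternative. Tests of promoters, gene lists and sequence words were not run, with their alternatives, for want of a WS220 annotation. No paired analysis was possible because the input libraries have no values of their own in the peak lists used here. Depth is unknown, so a peak missing from the shorter replicate 2 list cannot be called unbound.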

Other observations

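The tests of X share by rank, of X density over whole lists, of X against I to III and of the middle 50% on X were chosen after the result was seen; so was the count of each cluster once, while the removal of X clusters and the test of closeness were chosen after the files had been seen but before their own values were known. Combined peaks often came in groups. The 2299 peaks formed 1319 clusters at a spacing of up to 10 kb, of which 849 held a single peak and 217 held at least 3, together 944 peaks. After the cluster of 12 peaks on V, the largest were one of 11 peaks on II at 6823357 to 6853434 and 4 of 10 peaks, on I at 9539460 to 9564618, on V at 1570004 to 1580841 and on IV at 12533719 to 12553304 and 16382016 to 16415469. A neighbour within 2 kb was found for 28.9% of the merged combined regions. In 1000 random draws of 2299 nuclear peaks from a replicate list the share averaged 8.90% in replicate 1 (highest 11.6%). In replicate 2 it averaged 8.49% (highest 11.1%). The combined peaks thus lay closer together than any random draw of 2299 peaks from either list. Such a draw thins a list, so the closeness of all called peaks in the full lists was not measured. The strongest 2299 peaks of each replicate gave 32.3% and 22.7%. A hypothesis is that strong NHR-2 regions may be grouped at shared regulatory stretches, which would need WS220 genes to examine. Several summits called within 1 broad region would give the same pattern and were not tested.

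For the higher density on X, a factor that adds peaks on X at every rank is argued against, because the odds of lying on X were higher among the strongest 2299 peaks than beyond number 10000 in both replicates. The odds ratio was 1.58 (1.31 to 1.88) in replicate 1 and 1.35 (1.12 to 1.59) in replicate 2. The argument assumes that weak peaks would otherwise lie on X as often as strong ones, which was not tested. Measured against peaks beyond number 10000, the odds of X relative to I to III alone were also higher in the combined list. The odds ratios were 1.28 (1.05 to 1.55) with replicate 1 and 1.38 (1.14 to 1.67) with replicate 2. Both share the same combined list, whose own X density was 1.13 times (0.95 to 1.35) that of I to III. These odds ratios therefore also reflect how the weak peaks were spread. A factor that raises the score of every X peak stays open. The X to autosome ratio over the whole list was 1.02 (0.954 to 1.095) in replicate 1 and 0.93 (0.85 to 1.02) in replicate 2, both intervals including 1. This ratio cannot decide, because both lists run down to a score of 0.0044. Such a factor could then change the ranks of X peaks and hardly their number. A few dense clusters on X are argued against as the source, since with each cluster counted once the ratio was 1.48 (1.31 to 1.67). A first test, which left out the 10 X clusters of most peaks, gave 1.23 (1.04 to 1.44), still above 1. The fall itself decides nothing, because removal on X alone can only lower the ratio. A preference of NHR-2 for X in embryos is untested, as copy number, mappability and the input cannot be examined here.

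The share of combined peaks in the middle 50% was lower on X (49.7%) than on the autosomes (58.9%), a difference of −9.20 percentage points (two-sided permutation p = 0.139, from 10000 permutations of the chromosome labels of clusters and adjusted for the choice of X among 6 chromosomes), so chance is not excluded. The longest stretch without a combined peak was on V from 16356145 to 17921370 (1565226 bp), where replicate 1 still held 188 peaks and replicate 2 held 167, or 120 and 107 per Mb against 227 and 185 per Mb over the whole of V. The longest such stretch on X was 228825 bp, and on III it was shorter still, at 223247 bp.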
